A study of Sus scrofa with 20 samples.

How the data were processed

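The samples were total RNA from PBMCs of pigs, separated from whole blood on a density gradient and made into small RNA libraries with the NEBNext small RNA kit, per the labels' protocols. The 10 Control and 10 ICH samples were assigned from the sample titles, which also give the replicate numbers. The design text of the series describes a first sample just before ICH and another 6 h later. No sequencing batches are given in the labels.

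The deposited count tables hold whole-number read counts per miRNA and library against pig and human miRNA references, with a filtered version of each. The submitters' processing notes name bcl2fastq, FastQC and Bowtie, without versions, and the builds Sscrofa11.1, GRCh38 and hg38. The rules for counting, for reads that fit several miRNAs and for the filter are not given in the sources used here. The unfiltered tables hold 284 pig and 608 human miRNAs and the filtered ones 226 and 336. The filter kept 99.6% to 99.8% of reads and lowered some individual counts. The deposited RPM values were, on checking, the filtered counts divided by their library total, within 0.005. Names ending in @ (4 in the pig tables, 3 in the human) join several miRNAs, and what was joined is not stated. The pig-reference tables used here have no entry for miR-223, so the ratio of miR-223 to miR-150 was taken from the human-reference counts; the plan had assumed the pig table.

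Tests were run on the unfiltered counts in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM scaling, robust quasi-likelihood fit), and P values were adjusted by Benjamini-Hochberg over the miRNAs tested, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the fold change and the F statistic. CPM of single miRNAs are edgeR's, with TMM-scaled library sizes, and so differ from plain shares of reads; log2 CPM and the counts of pairs higher or lower use them too, with a prior count. The ratios used log2 of CPM plus 1, from library totals without TMM, and a two-sided permutation test with 100000 resamples, with the exact sign-flip test within pairs beside it. Ratios of hairpin arms used the same CPM, with limma on the differences within pairs. List tests used camera in limma 3.58.1 on voom values with a preset correlation of 0.01, with the estimated correlation and fry beside it, over the 9 lists with at least 3 tested members. camera compares a list with the other miRNAs, and fry does not. List members were matched by name without species and arm. The lists share members: miR-126 is in the platelet and vessel wall lists, miR-9 in the NF-kB and brain lists, and miR-363 in the erythroid and miR-17-92 lists. Figures were drawn with matplotlib 3.10.9.

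The plan set the fit without a block as the primary one and the replicate number as a block as an alternative. Samples with the same number deviated together from their group means, with correlations of 0.129 to 0.768 in the pig-reference counts and all 10 over the preset minimum of 0.1, against a median of -0.065 between different numbers. For 7 of the 10 numbers the Control and ICH samples were each other's best match, and for the rest they were not. With the design text, the numbers were taken to pair the samples, and blocked values are printed where the block changes a call or a count. The correlations and the calls of both fits were first seen together. The common dispersion was 0.074 without the block and 0.0308 with it.

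The miRNAs named were chosen by a rule set before the data were examined. In the pig-reference counts the rule took, among called miRNAs with a mean of at least 10 CPM, the 10 largest rises and 10 largest falls and the 5 most abundant, and with no call in a direction the 3 smallest p values there. It added a fixed set and the 2 members of each list with the smallest p. In the human-reference counts it took 5 and 5 among names not tested in the pig table. Applying it to the blocked fit was decided after the counts without the block were seen. Positions were taken from an NCBI RefSeq gene table of Sscrofa11.1, the pig build that the submitters name, by matching miRNA names to synonyms; 266 of 284 pig names matched. The table gives gene intervals and not exons, so "within" means inside the interval of another gene.

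The libraries held 896960 to 2103685 pig-reference reads. Reads without molecular identifiers are not independent molecules. Without the block, the errors and p values cover the spread between libraries of a group, taken as independent. With the block, they cover the spread of the change within replicate numbers. The chi-square statistic per degree of freedom between libraries of one group was at least 19.5, so no 2 libraries of one group agreed within sampling noise. Control libraries were not compared with ICH libraries in this way. On simulated counts with 40 changed miRNAs (fewer than the tables' 179 and 245 tested), the pig-reference fit recovered 78% of 1.5-fold changes without the block and 92.7% with it, with 0% and 4.39% false calls. The human-reference fit recovered 65.3% and 86.4%, with 0.313% and 3.35% false. The simulated counts were given an effect shared by libraries of one replicate number, so the gain from the block was built in. It is no evidence for the pairing in the data. No change under 1.5-fold was simulated, so recovery of the smaller called changes is not shown. camera found a lymphocyte list lowered 1.4-fold in 20 of 20 simulations. These drew each miRNA independently and used the preset correlation. In the data the list's estimated correlation was 0.185 without the block and 0.172 with it, so the simulations do not show camera's power there.

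Alternatives tried were other scalings (DESeq2's size factors, upper quartile, library totals), other filters and the submitters' filtered counts, DESeq2 1.42.0, limma voom and limma on the deposited RPM, the replicate block or random effect, leaving out erythroid miRNAs, other pseudocounts, and leaving out each library. Thinning of reads, leaving out miR-21, the alternatives to the blocked fits and the comparison of hairpin arms were chosen after seeing the data.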

Results

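Small RNA libraries were made from peripheral blood mononuclear cells (PBMCs, the lymphocytes and monocytes that a density gradient separates from blood) of female American Yorkshire pigs. The blood was drawn before and 6 h after intracerebral hemorrhage (ICH), a bleed modelled by injecting the animal's own blood into the frontal white matter. There were 10 libraries from before the injection (Control) and 10 from 6 h after it (ICH), and the same replicate numbers, 1 to 10, occurred in both groups. The pig-reference table held 896960 to 2103685 reads per library, with means of 1349100 ± 375700 in Control and 1366200 ± 373200 in ICH (SD, n = 10 each; two-sided permutation test, p = 0.92). Counts of the same libraries against human miRNAs were deposited as well. No sham-operated animals were analysed here, so each comparison is of blood before with blood 6 h after.

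The first comparison asked which pig miRNAs differed between blood drawn before and 6 h after ICH. Compared within replicate numbers, miR-21, an miRNA induced in activated immune cells, rose 1.43-fold, and miR-126-3p, an miRNA of endothelial cells and platelets, rose 1.41-fold. Over the same interval miR-150, which is abundant in mature lymphocytes, fell to 0.732 of its earlier level. In the same fit miR-29a fell to 0.714, miR-125a to 0.663 and miR-132 to 0.638 of the level before ICH. Of 179 miRNAs tested with the replicate number as a block, 21 rose and 18 fell past an adjusted p of 0.05, and the called changes were 1.17-fold to 1.73-fold in size (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). The balance depended on the method, with 16 rising and 20 falling under library totals with the block and 19 and 21 with the replicate as a random effect in limma voom. Without the block, edgeR called 0 of 179. The smallest adjusted p was then 0.0505, 35 miRNAs had an unadjusted p under 0.05 (14 higher and 21 lower), DESeq2 called 11 and limma voom called 3. Every change named as a rise or fall in the pig-reference counts is therefore a result of the blocked fit.

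miR-21 was the most heavily sequenced of the miRNAs named. It took 13.21% ± 2.97 of pig-reference reads in Control and 17.97% ± 2.44 in ICH (SD, n = 10 each). A two-sided permutation test, which ignores the pairs, gave p = 0.00104. Its share was higher after ICH in 9 of 10 pairs (exact sign-flip test within pairs, p = 0.00586). Its log2 fold change was 0.52 ± 0.095 (SE; adjusted p = 0.00229, edgeR with the block), against 0.50 ± 0.13 (adjusted p = 0.0505) without it. The gene lies on chromosome 12 at 36065267 to 36065358 (Sscrofa11.1), inside no other annotated gene. miR-126-3p went from 318.0 ± 80.2 to 443.4 ± 82.7 CPM (SD, n = 10 each; CPM, counts scaled to TMM-adjusted library sizes) and was higher in 10 of 10 pairs (log2 fold change 0.50 ± 0.098 SE, adjusted p = 0.00232). Its gene lies within the interval of EGFL7, on a sequence with no assigned chromosome.

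**Figure D1:**
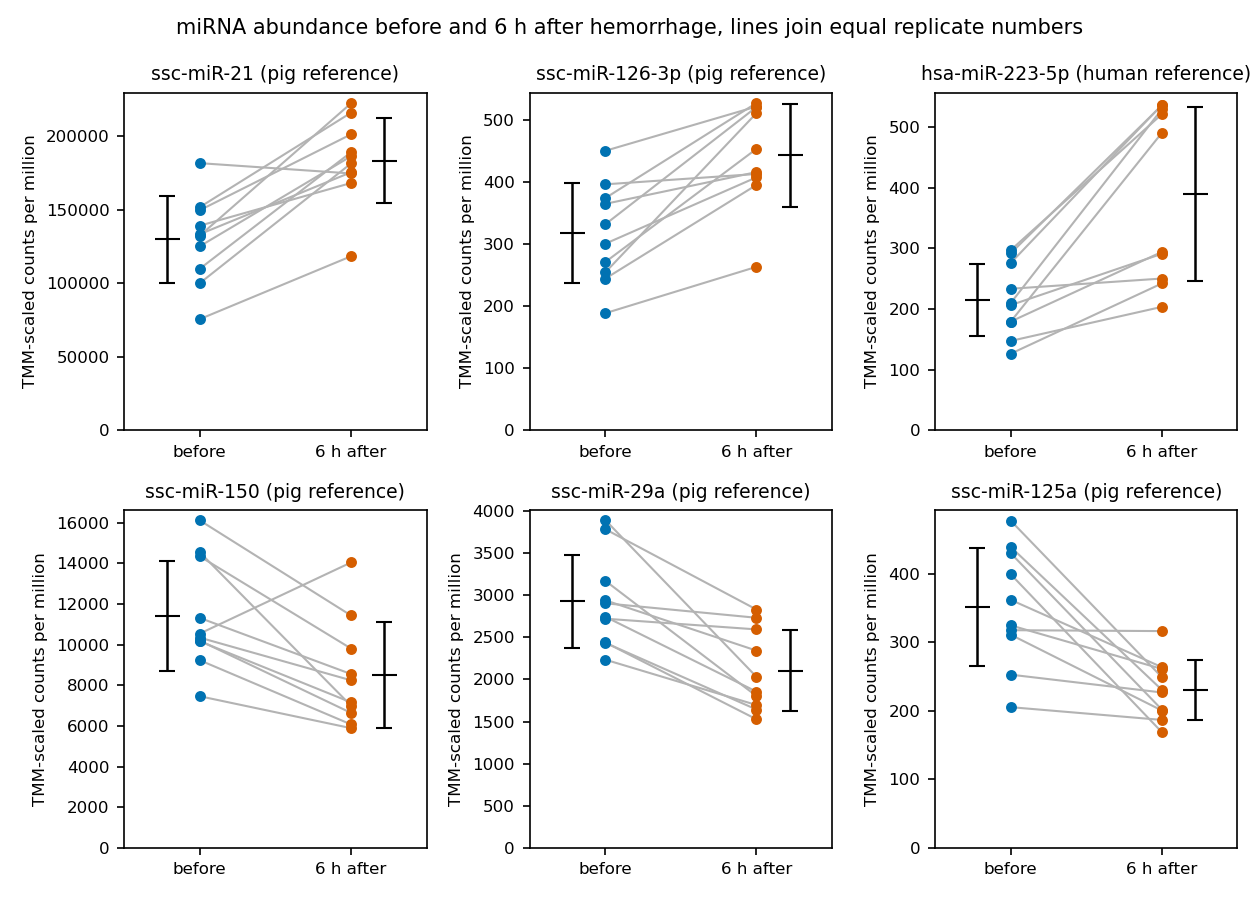
Abundance of 6 miRNAs in TMM-scaled CPM (vertical axes, from 0) before and 6 h after ICH. Points are libraries, lines join equal replicate numbers, and black marks give the mean and SD of 10 libraries; miR-29a was lower in 10 of 10 pairs, and miR-126-3p was higher in 10 of 10.

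Larger folds occurred among scarcer miRNAs. miR-582, whose gene lies within the interval of PDE4D on chromosome 16 (38580344 to 38580420), rose by 0.79 ± 0.23 on the log2 scale (SE; adjusted p = 0.0156), from 16.4 ± 7.07 to 29.6 ± 14.3 CPM (SD, n = 10 each). miR-504, within FGF13 on chromosome X, rose by 0.71 ± 0.15 (adjusted p = 0.00265). miR-7857-3p rose by 0.67 ± 0.12 and was higher in 10 of 10 pairs. miR-574, within FAM114A1 on chromosome 8, rose 1.53-fold, and miR-139-3p, within PDE2A on chromosome 9, rose by 0.59 ± 0.17 on the log2 scale. miR-7139-5p, miR-9841-3p, the merged entry miR-9@, miR-10a-5p and miR-148a-3p also rose, by 0.42 to 0.58 on the log2 scale. Among the abundant miRNAs, miR-148a-3p went from 7888 ± 2321 to 10470 ± 2874 CPM and was higher in 10 of 10 pairs.

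Of the miRNAs that fell, miR-31 had the largest change among those averaging at least 10 CPM, at -0.69 ± 0.16 on the log2 scale (SE; adjusted p = 0.00432). miR-132, on chromosome 12 at 48162625 to 48162702, was lower in 10 of 10 pairs (-0.65 ± 0.14, adjusted p = 0.00289). miR-95 fell by 0.64 ± 0.16 (adjusted p = 0.00658) and was lower in 9 of 10 pairs. miR-99b and miR-125a are neighbours on chromosome 6, starting at 58332211 and 58331566. miR-99b changed by -0.64 ± 0.13 and miR-125a by -0.59 ± 0.12, each with an adjusted p of 0.00245 and each lower in 10 of 10 pairs. miR-34c, miR-30b-5p and miR-151-5p fell by 0.47, 0.45 and 0.44 on the log2 scale. The abundant miR-142-5p, found across blood cell lineages, went from 16860 ± 4033 to 13550 ± 3151 CPM (adjusted p = 0.0264).

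Lists of miRNAs linked to cell types or programs were fixed before the data were examined, and some of them share members. In the lymphocyte list 6 of 12 tested members fell with the block, 1 rose and 5 did not pass the test. The 6 were miR-150, miR-181a, miR-181b, miR-29a, miR-29b and miR-31. miR-181d-5p rose by 0.44 ± 0.092 and was higher in 10 of 10 pairs; it was named after its values were seen. miR-342 did not pass (-0.40 ± 0.15, adjusted p = 0.0555). With the block and adjusted over the list alone, 7 fell and 1 rose, and without the block 4 fell and 1 rose. The list's median log2 fold change was -0.32 and its camera test with the preset correlation gave an adjusted p of 0.0303 without the block. The adjusted p was 0.698 with an estimated correlation, 0.0599 with the block and 0.527 with both. The fry test of a common direction gave an adjusted p of 0.0896 without the block and 0.0134 with it. Members of the miR-29 and miR-181 families have near-identical sequences, so the split of reads among them is uncertain.

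Lists for other blood cell types were tested in the same way. The pig-reference counts have no miR-223, so the myeloid list was tested there without it. In the myeloid list 0 of 7 pig members passed the test, with or without the block and also when adjusted over the list alone; miR-22-3p had a log2 fold change of 0.15 ± 0.075 and miR-24-1-5p of 0.12 ± 0.098. In the erythroid list 1 of 5 members rose, miR-486, whose gene lies within ANK1 on chromosome 17 (0.57 ± 0.13, adjusted p = 0.00398). miR-451 had a log2 fold change of 0.57 ± 0.27 (adjusted p = 0.158), miR-144 of 0.40 ± 0.15 (adjusted p = 0.065) and miR-16 of -0.27 ± 0.10 (adjusted p = 0.0555). Adjusted over the list alone with the block, 2 members rose and 2 fell. In the platelet list miR-126-3p rose, miR-151-5p and miR-151-3p fell, and 4 of 7 members did not pass. That list's fry test gave an adjusted p of 0.657 for a common direction and 0.000416 for change in either direction, both with the block. For a common direction of the myeloid and erythroid lists it gave 0.183 and 0.164. The log2 ratio of miR-451 to miR-23a within a library was higher after ICH in 8 of 10 pairs.

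**Figure D2:**
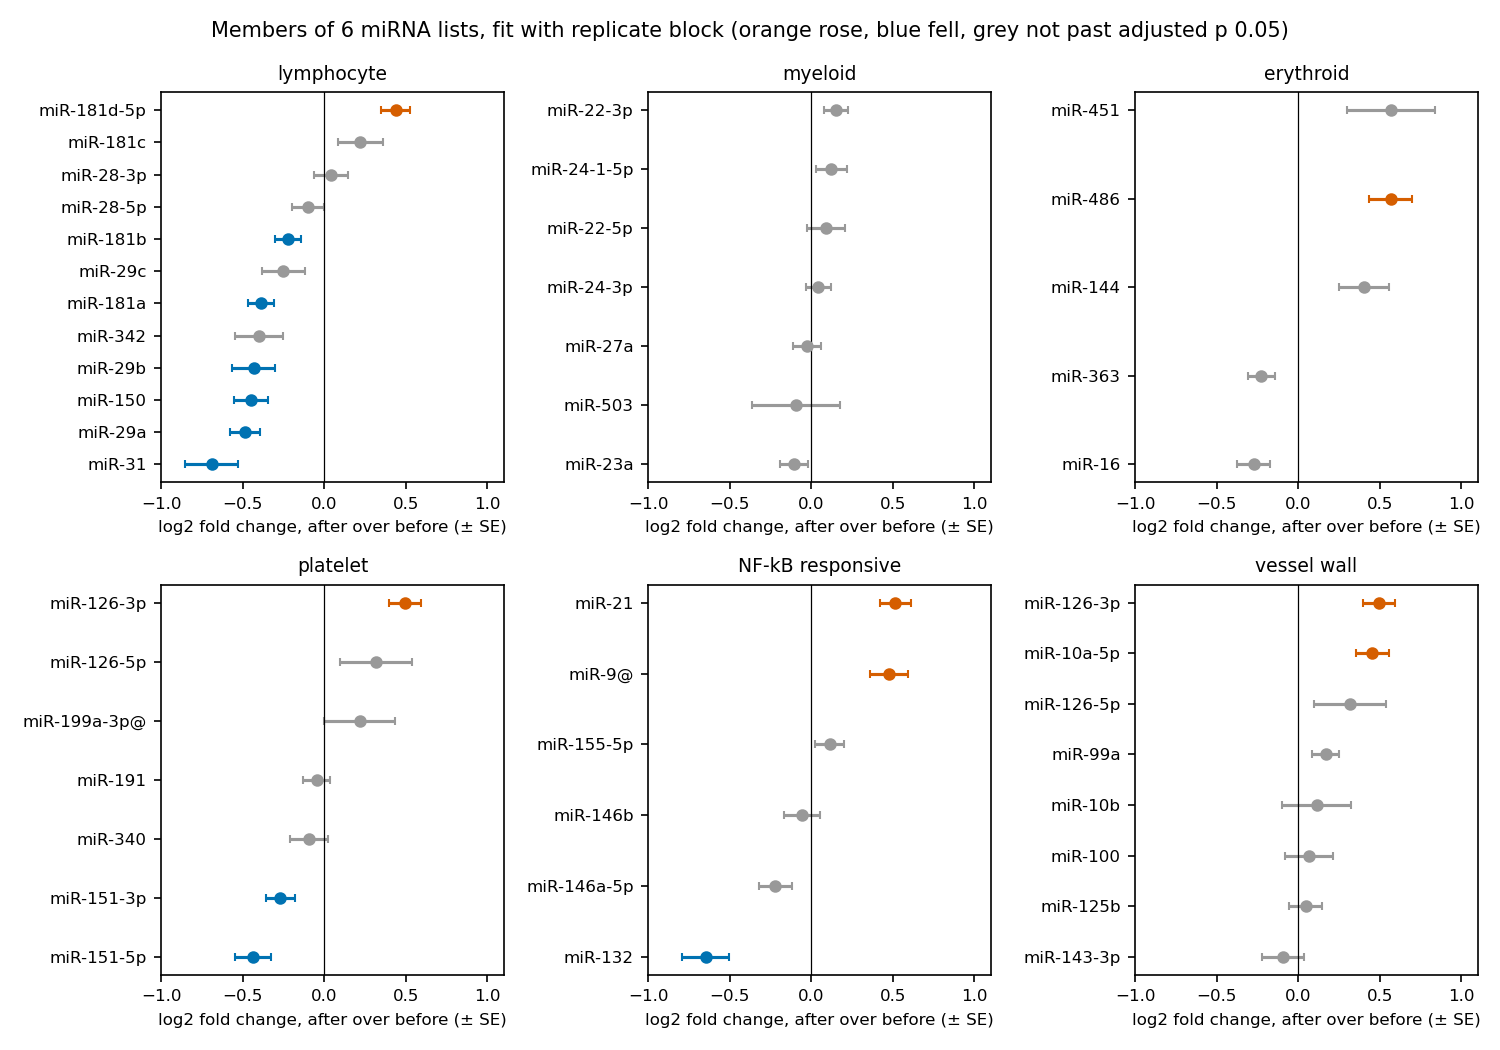
Log2 fold change 6 h after over before ICH (horizontal axes, with SE) of the tested members of 6 miRNA lists in the fit with the replicate number as a block. In the lymphocyte list 6 of 12 members fell and 1 rose, and in the myeloid list, which has no miR-223 here, 0 of 7 passed the test.

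Among miRNAs responsive to NF-kB, the transcription factor of inflammatory signalling, miR-21 and miR-9@ rose and miR-132 fell. The other 3 of 6 did not pass, with log2 fold changes of 0.11 ± 0.088 for miR-155-5p, -0.22 ± 0.10 for miR-146a-5p and -0.06 ± 0.11 for miR-146b. The count adjusted over the list alone with the block was also 2 rising and 1 falling, and the fry test gave an adjusted p of 0.149 for a common direction and 0.0012 for change in either direction. In the vessel wall list 2 of 8 members rose, miR-126-3p and miR-10a-5p. The list's median was 0.14, with an adjusted fry p of 0.00596 with the block and 0.291 without it, and an adjusted camera p of 0.115 with the block. With an estimated correlation, camera's adjusted p was 0.44 with the block and 0.698 without it. miR-182 and miR-183, neighbours on chromosome 18 at 18986830 and 18982269, both rose (0.55 ± 0.12 and 0.41 ± 0.14), and these were the 2 tested members of their cluster. Adjusted over the list alone with the block, the counts of the platelet, vessel wall, miR-183 and brain lists were the same as over all miRNAs tested. Without the block, camera's adjusted p of the 8 lists other than the lymphocyte list ran from 0.153 to 0.904.

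In the let-7 family 1 of 9 members rose, let-7c (0.31 ± 0.10, adjusted p = 0.0396). In the list of miR-17-92 and its paralogs 1 of 10 fell, miR-19b (-0.36 ± 0.12, adjusted p = 0.041). Adjusted over either of these lists alone, 0 passed. The fry test with the block gave an adjusted p of 0.548 for a common direction of the let-7 family and 0.113 for the miR-17-92 list, whose adjusted p for change in either direction was 0.012. Near-identical family members can share reads here too. In the brain list 1 of 3 rose, miR-9@, and miR-128 had a log2 fold change of 0.15 ± 0.11 (adjusted fry p = 0.082 with the block). The muscle list and the list of liver and gut miRNAs had 1 tested member each, miR-499-5p (-0.16 ± 0.084) and miR-192 (0.14 ± 0.12), and neither passed, also when adjusted over the list alone. No member of the DLK1-DIO3 or epithelial lists was tested in the pig-reference counts. miR-210, which responds to low oxygen, had a log2 fold change of 0.11 ± 0.10 (adjusted p = 0.484).

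The same libraries were then compared in the counts against human miRNAs, which name miRNAs that the pig-reference tables used here do not. These were largely the same reads, at 1.02 to 1.04 times the pig-reference totals, and are not independent evidence. Without the block, 7 of 245 miRNAs rose and 2 fell (edgeR, adjusted p under 0.05), and all 9 were also called with the block. Without the block, leaving out ICH 2, Control 3 or ICH 8, or using limma on the deposited RPM, left 0 rises and 1 fall, that of miR-203a-3p. miR-223-5p and miR-223-3p, products of a gene active in myeloid cells, rose by 0.86 ± 0.20 and 0.62 ± 0.17 on the log2 scale (SE; adjusted p = 0.0235 and 0.0263), and with the block by 0.82 ± 0.12 and 0.63 ± 0.15 (adjusted p = 6.75e-05 and 0.00856). miR-223-5p went from 214.7 ± 59.4 to 389.6 ± 143 CPM (SD, n = 10 each) and was higher in 10 of 10 pairs. miR-27a-5p rose by 0.78 ± 0.20, miR-582-3p by 1.04 ± 0.27 and miR-574-3p by 0.66 ± 0.18. miR-21-5p and miR-126-3p made up the 7, and were named after their values were seen. miR-203a-3p fell from 2347 ± 381 to 1709 ± 241 CPM and was lower in 10 of 10 pairs, and miR-125a-5p fell by 0.55 ± 0.15 on the log2 scale.

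With the block, 32 human-reference miRNAs rose and 15 fell. miR-504-5p (0.78 ± 0.16) and miR-4508 (0.76 ± 0.26) were among those that rose. miR-4508 was scarce, at a mean of 12.56 CPM, and lay near the threshold (edgeR, adjusted p = 0.0398). Whether reads of another RNA were counted as miR-4508 was not tested. Both arms of miR-132 fell (-0.58 ± 0.15 for 3p and -0.59 ± 0.21 for 5p), as did miR-31-5p (-0.61 ± 0.16), miR-95-3p and miR-99b-5p (each -0.57). The balance of rises and falls depended on the scaling between libraries. With library totals the split was 15 rising and 24 falling with the block and 2 rising and 3 falling without it. With DESeq2's size factors it was 28 and 19 with the block and 6 and 5 without it, and without the block the pig-reference library sizes gave 5 and 5.

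By list, 3 of 9 myeloid members rose in the human-reference counts with and without the block, miR-223-3p, miR-223-5p and miR-27a-5p. With the block, 5 of 18 lymphocyte members fell and 2 rose, and 2 of 8 erythroid members rose, miR-486-5p and miR-144-3p. Adjusted over the list alone, 4 myeloid members rose, 7 lymphocyte members fell and 2 rose, and 3 erythroid members rose. In the NF-kB list 3 of 10 rose (miR-21-5p, miR-9-5p and miR-147b) and both arms of miR-132 fell. In the platelet list 1 of 8 rose and 1 fell, in the vessel wall list 2 of 9 rose, in the let-7 family 1 of 17 rose and in the brain list 1 of 5 rose. Both members of the miR-183 cluster rose, and 0 of 20 members of the miR-17-92 list passed. The muscle list and the liver and gut list each had 1 tested member, which did not pass. Of the 2 epithelial members tested, miR-203a-3p fell and miR-200c-3p rose with the block (0.43 ± 0.15, adjusted p = 0.045); the latter was named after its values were seen. Across 64 miRNAs with the same name and arm in both tables, log2 fold changes without the block correlated with Pearson's r = 0.989 and Spearman's rho = 0.977. This correlation is across miRNAs, which are not independent replicates.

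The last comparison used ratios within a library, which need no scaling between libraries. The log2 ratio of miR-223-3p to miR-150-5p was planned as an index of myeloid over lymphoid miRNAs and taken from the human-reference counts. No cell counts were used, so it does not measure the balance of the cells themselves. The log2 ratio was -3.16 ± 0.39 in Control and -2.15 ± 0.32 in ICH (SD, n = 10 each). The ratio was 2.02-fold higher after ICH (two-sided permutation test, p = 2e-05, adjusted p = 4e-05 over 2 ratios) and was higher in 10 of 10 pairs. The exact sign-flip test within pairs gave p = 0.00195, the smallest it can give. The log2 ratio of miR-451 to miR-23a was planned as an index of red cell RNA. miR-23a is itself in the myeloid list, so the ratio does not follow red cell RNA alone. This second log2 ratio was -3.80 ± 1.26 in Control and -3.06 ± 0.77 in ICH. That difference of 0.74 did not pass the two-sided permutation test, which ignores the pairs (p = 0.13). Within pairs the exact sign-flip test gave p = 0.0254, with 8 of 10 pairs higher. The largest rise was in number 4, from -5.96 to -2.79, and number 10 hardly changed, from -2.738 to -2.723.

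**Figure D3:**
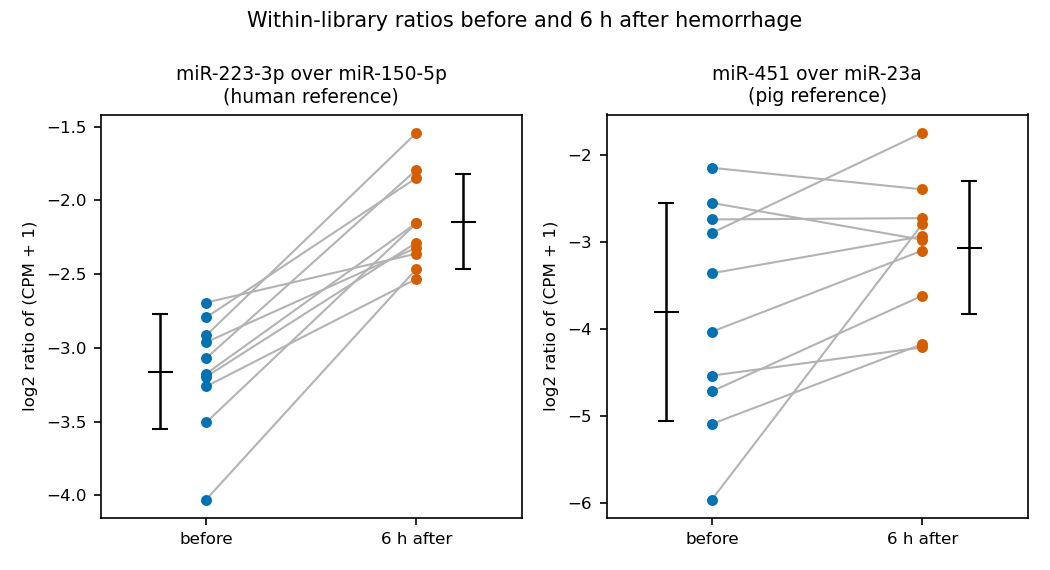
Within-library log2 ratios of CPM from library totals, each with 1 added, before and 6 h after ICH (vertical axes). Points are libraries, lines join equal replicate numbers, and black marks give the mean and SD of 10 libraries; the ratio of miR-223-3p to miR-150-5p was higher in 10 of 10 pairs and that of miR-451 to miR-23a in 8 of 10.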

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

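In 130 groups of 10 libraries (the named miRNAs, ratios, read totals and the miR-21 share), 6 had a library set apart from its nearest neighbour by more of the group's range than Dixon's 95% critical value allows; chance gives about 1 in 20. ICH replicate 4 was the low library in 3 of them. Its miR-126-3p was 8.051 log2 CPM against 8.634 to 9.048 in the other ICH libraries, its miR-22-3p was 11.76 against 12.1 to 12.4, and its miR-486 was 6.059 against 6.967 to 7.991. Control replicate 4 was low for miR-144, at 4.743 against 6.155 to 7.637. ICH replicate 1 was low for miR-21, at 16.85 against 17.36 to 17.76. Control replicate 10 was low for miR-151-5p, at 5.911 against 6.475 to 7.005. Without replicate number 4, the blocked pig-reference fit called 35 rises and 24 falls, and 37 of the original 39 calls were among these 59.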

How the results depend on the processing

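Alternatives to the blocked fits, thinning and the arm comparison's pseudocount were chosen after seeing the data. The pig-reference count without a block was 0 of 179 and became 2 with library totals, 3 with upper-quartile scaling, 11 with DESeq2 (11 adjusted p not given), 3 with limma voom, 39 with the replicate block, 46 with DESeq2 with replicate block and 40 with the replicate as a random effect (correlation 0.475); it stayed at 0 under the other alternatives. The smallest adjusted p of 0.0505 lay next to the threshold. Leaving out 1 library gave 0 to 14 calls: 4 without ICH 1, 14 without ICH 4, 2 without Control 5, 8 without ICH 5, 2 without ICH 6, 12 without Control 8, 11 without Control 9 and 6 without Control 10. With the block the pig count was 39, 0 with no replicate block, 30 to 46 under the other alternatives and 27 to 59 without 1 replicate number (59 without number 4). The share of rises was 53.8%. It became 44.4% with library totals (16 rising, 20 falling), 63.3% with library totals and miR-21 left out, 65.9% with no filter, 60.5% with the submitters' filter and 65.8% after thinning, and was 47.5% with the random effect (19 and 21).

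The human-reference count of 9 became 5 with library totals, 1 with limma on RPM and 47 with the replicate block, and 1 to 18 without 1 library: 5 without Control 1, 1 without ICH 2, 1 without Control 3, 18 without ICH 4, 16 without ICH 5, 5 without Control 7, 17 without Control 8, 1 without ICH 8 and 2 without Control 10. Each single call was the fall of miR-203a-3p, so all 7 rises were lost there. With the block the count was 47, 9 with no replicate block, 31 with miR-21 left out and library totals, and 32 to 61 without 1 replicate number. Upper-quartile scaling moved the median pig log2 fold change by 0.117, and library totals and RPM moved the human median by -0.109 and -0.105. The cause of these changes was not tested.

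The miR-223 to miR-150 log2 ratio kept its direction and call, at 1.011 with a pseudocount of 10 and 0.9186 to 1.067 without 1 library; another reference, set out beforehand, was not run. The miR-451 to miR-23a log2 ratio was 0.7365, past the threshold only with the replicate block, and 0.4966 to 0.9207 without 1 library. Of the lists, 1 was called by camera, 0 with an estimated correlation and 0 with the replicate block. Neither miR-146b nor miR-23a was called; miR-146b was 0.052 and miR-23a 0.00995 under upper-quartile scaling, and miR-146b was 0.030 without Control 6 (-0.10 to 0.030 over the libraries left out).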

Other observations

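The tests of hairpin arms, of neighbours, of lymphocyte share and of the falling miRNAs after thinning were chosen after the results were seen. In the human-reference counts, both arms were tested for 57 hairpins, and the 5p over 3p log2 ratio changed within pairs for 1 of them, miR-27a (limma, adjusted p = 0.0104; 0.00379 with a pseudocount of 10). The ratio rose by 0.68 ± 0.14 (SE) and was higher in 10 of 10 pairs. miR-27a-5p had a log2 fold change of 0.73 ± 0.11 with the block, and miR-27a-3p, the other arm of the same precursor, had 0.043 ± 0.087 (adjusted p = 0.819). Whether reads of another RNA were counted as miR-27a-5p was not tested.

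Other human-reference miRNAs called with the block were named after their values were seen. miR-147b, which is induced in stimulated macrophages, rose by 0.60 ± 0.16 (adjusted p = 0.011) and was higher in 9 of 10 pairs. miR-139-5p rose by 0.57 ± 0.10 and miR-181c-3p by 0.41 ± 0.11, each higher in 10 of 10 pairs. miR-185-5p went from 6398 ± 1889 to 8037 ± 1598 CPM and miR-378a-3p from 3714 ± 950 to 4582 ± 1077 CPM (SD, n = 10 each; adjusted p = 0.0302 each, edgeR with the block). In the pig-reference counts with the block, neither miR-185 (0.29, adjusted p = 0.078) nor miR-378 (0.25, adjusted p = 0.0689) passed. The reverse occurred too, among miRNAs that fell in the pig-reference counts. In the human-reference counts with the block, miR-142-5p (-0.254, adjusted p = 0.0617) and miR-181b-5p (-0.159, adjusted p = 0.21) did not pass. Across the 64 miRNAs with the same name and arm, human-reference log2 fold changes with the block averaged 0.0593 above the pig-reference ones. miR-185-5p (0.356) and miR-378a-3p (0.308) likewise lay above their pig-reference values. So did miR-142-5p and miR-181b-5p, with pig-reference values of -0.3196 and -0.2248. The differing calls thus went with a shift between the references and do not mark changes particular to either.

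For the pig-reference counts without a block the real count was 0, which all 100 of 100 splits of the 20 libraries reach by construction, so the splits say nothing about chance there. The highest other split gave 42 calls in the pig and 44 in the human counts, against real counts of 0 and 9, which points to a structure of the samples that was not identified. The human-reference count of 9 was reached by 2 of 100 splits, the real one included. The other gave 44 calls and such splits do not keep to the pairs, so this does not exclude chance. Among 100 splits that part every pair, 1 reached it, the real one, and the highest other gave 0. With the block, 1 of 100 within-pair swaps, the real one, reached the pig count of 39 (highest other 8). For the human count of 47 it was also 1, the real one (highest other 18). That is the smallest share that 100 swaps can give, so counts this high were rare under swaps. After thinning every library to 896960 reads, 87.18% of the 39 pig calls remained.

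The fall of 18 pig miRNAs, 6 of them in the lymphocyte list, was weighed against 3 explanations. A larger share of reads taken by miR-21 could account for only a small part of the fall. With library totals that left out miR-21 the median of the 18 was -0.4143 (quartiles -0.591 and -0.33), and 11 remained called. The median was -0.495 with library totals that kept miR-21 and -0.449 with TMM scaling. Leaving out miR-21 shifts every fold change by about the same amount, set by its share. The comparison therefore gives the size of that part and is not an independent test. A difference in depth was argued against by the totals themselves, with means of 1349100 reads in Control and 1366200 in ICH (two-sided permutation test, p = 0.92). With depths so alike, thinning could decide little. After it the median was -0.3833 and 13 remained called, of 17 still tested. A lower share of lymphocytes among the cells may underlie the fall of the lymphocyte list and cannot be told apart from regulation within cells: the lowest median of the myeloid, erythroid and platelet lists was -0.04677, their members went both ways, other cell types also express many of them, and no cell counts were used here. A response of the blood cells to ICH also stays open, as do anesthesia, surgery and time, none of which was tested.

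miRNAs of different number whose genes lie within 10 kb of each other differed less in their changes than miRNAs paired at random. Over 59 pairs of 48 miRNAs the mean absolute difference in log2 fold change was 0.163, against a median of 0.264 when changes were reassigned at random (one-sided permutation p = 0.00033), and 43 pairs had the same direction. Reads shared between near-identical miRNAs were argued against as the whole cause, since without pairs inside the miR-17-92 list or of near-identical miRNAs the difference was 0.158 over 26 pairs against 0.307 (p = 0.00015). Only 16 of these 26 pairs had the same direction, so most of the agreement in direction came from the pairs left out. Processing from one shared primary transcript is a candidate explanation, as for miR-182 with miR-183. It does not cover let-7e, which lies between miR-125a and miR-99b and had a log2 fold change of -0.16 ± 0.11 (adjusted p = 0.318) against -0.59 and -0.64. These were tested on the data that showed the pattern, and pairs within a cluster are not independent.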
